A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

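The series holds 8 Affymetrix Yeast_2 arrays of biotin-labelled total RNA from S. pombe, 2 for each of 4 groups formed by strain (wild type or pap1 deletion) and by donor (active or decomposed detaNONOate). Groups and replicate numbers were taken from the sample titles. The deposited values are log2 expression summaries per probe set that the authors made with RMA, per the submitters' processing notes, which give no version. Raw image files were not used. The values were used without further scaling.

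The array carries 10928 probe sets, of which 2914 were named with a single S. pombe gene, 2601 for S. cerevisiae, 20 with several genes and 5390 with no gene. Symbols were brought up to date through locus tags for 113 genes. Where 14 genes had more than 1 probe set, the one with the highest mean over the 8 arrays was used, which left 2896 genes of 5124 protein-coding genes in the reference table. Of these 10 lay on a probe set shared with another gene and are not named. The background level was the 95th percentile of the means of S. cerevisiae probe sets, 3.41 on the log2 scale, and 2812 genes lay above it.

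Fits were made in R 4.3.3 with limma 3.58.1: lmFit with 1 mean per group and eBayes without trend, over all 8 arrays, with 4 residual degrees of freedom and 3.07 prior degrees of freedom. The 5 contrasts were treated against control in wild type, treated against control in the pap1 deletion, the difference between these, and the deletion against wild type in control and in treated cells. A gene was said to change at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Standard errors are limma's moderated ones, and n is 2 arrays per group; this number limits the precision. The 2 strains had no shared arrays, so their responses were compared over genes by correlation, slope and overlap, without a p.

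In all 24 gene lists were fixed, 23 of which had at least 5 measured genes and were tested in each contrast with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists. Camera with an estimated correlation and fry were run beside it; fry asks whether a list's genes move one way and does not compare them with other genes. Some members that matched only through an older or shared name were left out of their list by name alone. These were csm1 from the zinc and copper list, nhe1 from the antioxidant list, ssp1 from the chaperones and tbp1 from the proteasome list. Also left out were str1 from the sulfur list, and dip1, spb70 and rlp1 from ribosome biogenesis. The deleted gene pap1 was left out of the stress regulators. These members were taken out after fold changes of single genes, csm1 and tbp1 among them, had been seen. Other members matched through another name were kept, among them tim18 (iron-sulfur and heme, respiration), rad55 (DNA repair) and txl1 (antioxidant).

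Genes were named by a fixed rule. For each treatment contrast these were the 10 genes with the largest rise and the 10 with the largest fall past the threshold whose treated arrays both lay on the same side of both control arrays, and for the other contrasts the 5 largest each way, for the interaction without the condition on arrays. To these were added up to 4 members of each list with the largest changes past the threshold (values are given for part of these), pap1, and ctt1, trr1, srx1, tpx1, obr1, caf5, pgr1, hsp9, hsp16, gpx1, gpd1, ntp1, zym1, atf1, sty1 and cdc25 in every contrast. The groups, contrasts, lists before these removals, rule and most alternatives were chosen before the data were examined.

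The 3' to 5' index of an array was the median over 7 control transcripts of the 3' minus the 5' probe set. These are S. pombe transcripts and not added RNAs, so their own levels can change. The RIP1 3' probe set read 11.03 in wild type control and 9.79 in wild type treated arrays. In most arrays the median was the RIP1 value itself, and rip1 is a member of tested lists. The index is therefore not independent of the genes judged with it. A fit with 1 treatment effect, 1 strain effect and the index as a covariate gave the common effects named with the index. It has no interaction, because 4 free group means would leave the index only its spread between replicates. The index therefore takes up most of any difference in response between the strains, whatever its cause. A changed sign in this fit can arise where both strains moved the same way and the deletion moved less. Such a change need not be seen in either strain. The steps were tested on simulated data made from the real means and spreads. For treated against control in wild type, over 2896 genes of which 200 were changed, 77.6%, 98.5% and 100% of genes changed by 0.3, 0.6 and 1 (log2) were recovered and 4 unchanged genes were called. In the fit with the index over the same genes 7.46%, 65.7% and 95.5% were recovered and 5 unchanged genes called. These simulated values followed that fit's own model, with 1 index for all genes and equal treatment effects in both strains. They do not show how the fit does where transcripts or strains differ in scale.

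Alternatives tried were trend and robust variance, only the groups of a contrast in the fit, the replicate number as a block, arrays centred on the median S. pombe gene, quantile normalization over S. pombe genes, genes above background, all probe sets, the mean of a gene's probe sets, a 2-fold minimum, array weights and each array left out. Added after seeing the data were the index as a covariate, a fit without the treated wild type arrays, crossed replicate numbers and quantile normalization for the gene lists. Probe sets of other organisms or with no gene name were used as background and kept out of the comparisons.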

Results

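Transcript levels were measured in fission yeast, Schizosaccharomyces pombe, after a short exposure to nitric oxide. Wild type cells and cells with the pap1 gene deleted were suspended in phosphate-buffered saline and given 3 mM detaNONOate, a compound that releases nitric oxide as it decays, for 15 min at 30 °C. Control cells received the same compound after it had decomposed. Biotin-labelled RNA was hybridized to 8 Affymetrix yeast arrays, 2 for each of 4 groups: wild type control, wild type treated, pap1 deletion control and pap1 deletion treated. The labels call the 2 arrays of a group biological replicates, and state that the control and treated cells came from the same flask. Pap1 is a bZIP transcription factor of the oxidative stress response, and the study asked which genes respond to nitric oxide and which of these responses need Pap1. Of 10928 probe sets on the array, 2896 S. pombe genes had a named probe set and were compared. The median log2 value of an array lay between 3.07 and 3.26 over all probe sets and between 7.85 and 7.96 over the S. pombe genes. The number of arrays, 2 per group, limits the precision of every value.

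The deleted gene itself was read in every array. The pap1 probe set gave log2 values of 9.90 and 9.93 in the wild type control arrays and 10.11 and 10.09 in the treated wild type arrays. In the deletion strain it gave 2.33 and 2.35 in control arrays and 2.14 and 2.20 in treated arrays, all under the background level of 3.41, which is the 95th percentile of probe sets for the other yeast on the array. The array labels and the signal of pap1 therefore went together in all 8 arrays. In wild type cells pap1 rose by 0.19 ± 0.04 (log2, SE, n = 2 per group) under detaNONOate (adjusted p = 0.00427). The limma fit described next, with the signal balance along transcripts as a covariate, gave -0.51 (adjusted p = 0.0136). That fit has 1 treatment effect for both strains and so includes the deletion arrays, where pap1 was under background. The -0.51 therefore does not measure pap1 in wild type cells.

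Treated arrays differed from control arrays in the balance of signal along control transcripts. Labelling of these targets starts at the 3' end of a transcript, so the 3' signal minus the 5' signal of a control transcript measures how far labelled targets extend. The median of this difference over 7 control transcripts, here called the 3' to 5' index, was 1.34 ± 0.08 (log2, mean ± SD, n = 2) in wild type control arrays and 3.35 ± 0.02 in wild type treated arrays, a shift of 2.01. In the pap1 deletion it was 1.65 ± 0.01 and 2.64 ± 0.12, a shift of 0.99. The actin transcript ACT1 shifted by 3.55 in wild type and 1.45 in the deletion, and RIP1 by 1.97 and 1.00. TFIID moved the other way, by -1.59 and -1.01. All 7 are transcripts of S. pombe itself, and in most arrays the median was the RIP1 value. The index differed between all compared groups, so its shift is given with each comparison. A limma fit with the index as a covariate, chosen after the index had been seen, gave 1 treatment effect common to both strains and 1 strain effect common to both treatments. Without an interaction, most of any difference in response between the strains is assigned to the index. A sign that changes there can mean only that the deletion changed less than wild type. For lists that camera called, outside the interaction, the result of that fit is given as well. Camera with an estimated correlation, given beside the calls, tests on the 4 residual degrees of freedom, so few lists can pass in it.

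**Figure D1:**
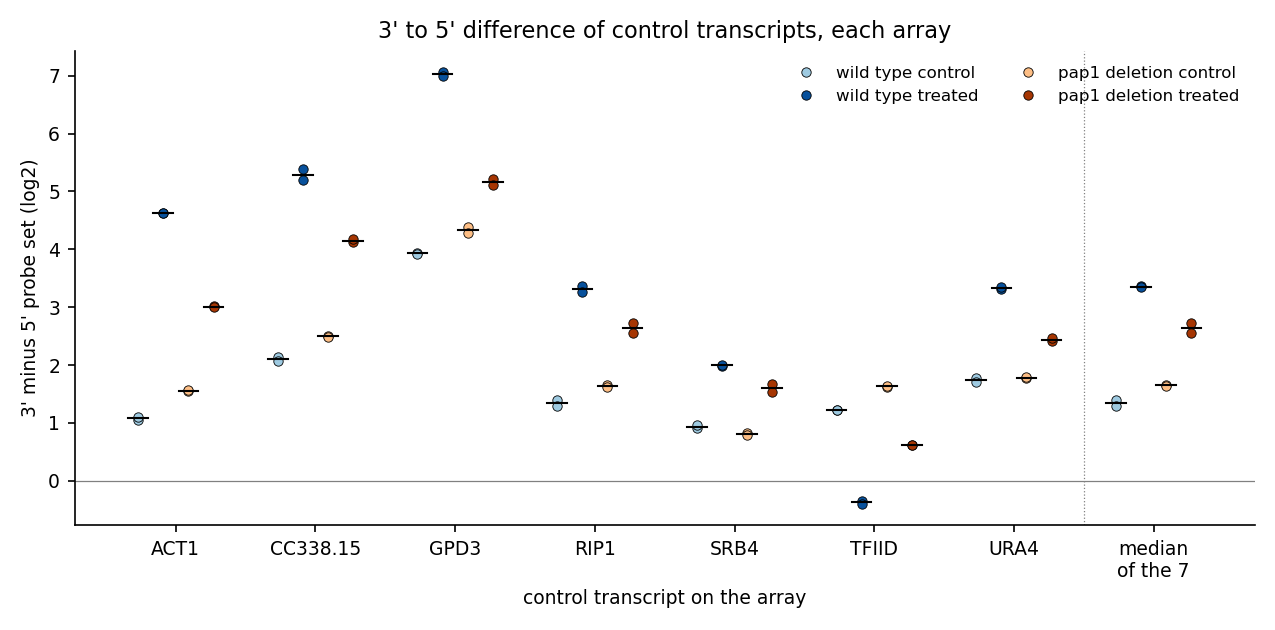
The 3' minus 5' signal (log2) of each of the 7 control transcripts is plotted for each of the 8 arrays, with the median over transcripts in the last column. Short lines mark the mean of the 2 arrays of a group. The median lies at 1.34 in wild type control, 3.35 in wild type treated, 1.65 in pap1 deletion control and 2.64 in pap1 deletion treated arrays.

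The comparison of treated with control wild type cells asked how nitric oxide changed gene expression when Pap1 was present. The transcription factors of the general stress response were among the genes that fell. The message of atf1, which encodes the bZIP factor at the end of the Sty1 stress kinase pathway, fell by 3.28-fold (log2 -1.71 ± 0.08, SE, n = 2 per group, adjusted p = 7.9e-07), and that of its partner pcr1 fell by 4.93-fold (-2.30 ± 0.06). The related factor atf21 fell by 2.61 ± 0.13, to a treated mean of 3.61 near the background level of 3.41. The steepest falls were in erg31, a C-5 sterol desaturase (-3.51 ± 0.09), the syntaxin psy1 (-3.30 ± 0.08), the NEDD8 protease gene nep2 (-3.07 ± 0.08) and the TATA-binding protein gene tbp1 (-3.05 ± 0.05). The next falls were in rds1, sap1, psu1, coq10, htb1 and sck2, from -2.96 to -2.85, the last to a treated mean of 3.65 near background. The largest rises were smaller: pop8, a subunit of RNase P (1.83 ± 0.08), the dynactin subunit ssm4 (1.82, a lower bound, with a control mean of 3.27 under background), the monopolin subunit csm1 (1.82 ± 0.06) and cog5 of the Golgi tethering complex (1.81 ± 0.06). They were followed by atl1, the M-factor precursor gene mfm2, mhf1, stc1, sgo1 and mrpl44, from 1.72 down to 1.55. In limma, 1174 genes rose and 1149 fell of 2896 tested, and 160 rose and 359 fell by at least 2-fold. The split was 1359 and 1039 with arrays centred on the median S. pombe gene, and 1351 and 1023 after quantile normalization over the S. pombe genes. The index was 2.01 higher in the same treated arrays. In the fit with the index as a covariate 511 genes were higher and 310 lower. There atf1 stood at -1.52, pcr1 at -1.03 and mfm2 at 1.26. In the same fit erg31 (0.72), psu1 (0.046), coq10 (0.73), htb1 (0.54), pop8 (-0.14), csm1 (-0.33), mhf1 (-0.26), stc1 (-0.020) and mrpl44 (-0.069) changed sign without passing the threshold.

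**Figure D2:**
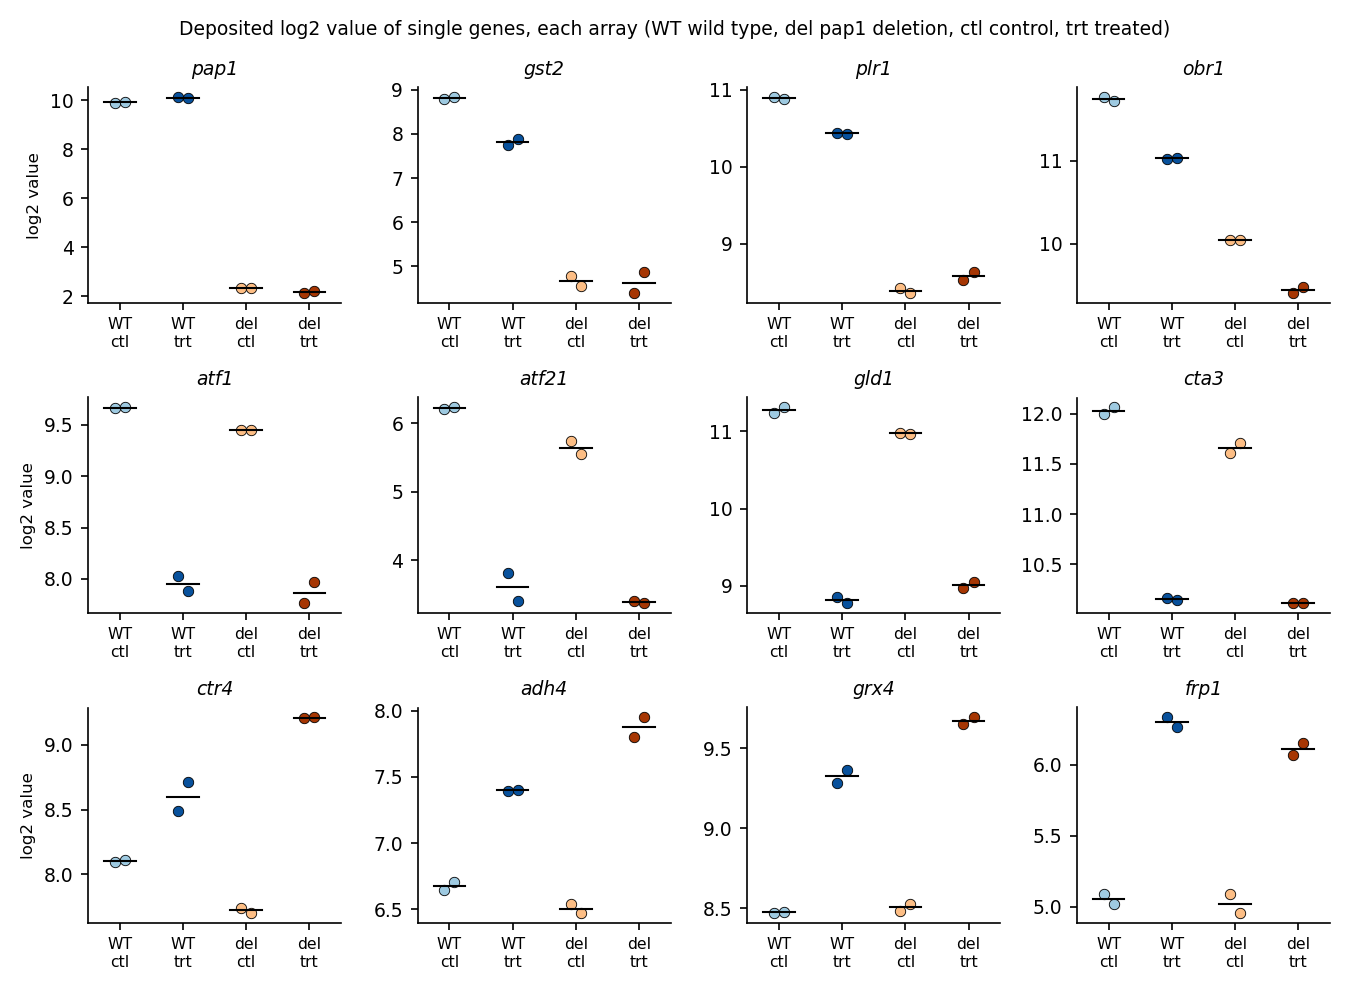
Log2 values of 12 genes are plotted for each of the 8 arrays, grouped by strain and treatment, with the group mean as a line. The stress factor atf1 falls from 9.67 to 7.96 in wild type and from 9.45 to 7.87 in the pap1 deletion.

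Stress genes mostly fell in wild type cells. Of the stress kinases and transcription factors, 35 of 38 fell and 3 rose, with a median of -0.91. They included the Sty1-activated kinase srk1 (-2.44 ± 0.04), sck2 (-2.85 ± 0.06) and sty1 itself (-1.21 ± 0.06). In the list of genes that environmental stress induces, 2 of 23 rose, 17 fell and 4 did not pass, with a median of -0.93. The cation ATPase cta3 fell by 3.66-fold (-1.87 ± 0.05), glycerol-3-phosphate dehydrogenase gpd1 by 2.83-fold (-1.50 ± 0.05) and the trehalase ntp1 by 2.33-fold (-1.22 ± 0.04). The small heat shock genes hsp9 (-0.23 ± 0.04) and hsp16 (-0.18 ± 0.04) fell slightly. The control mean of hsp9, 13.63, lay near the highest value of wild type control array 1, 13.67. The size of its change is therefore uncertain in every comparison. Among chaperones 2 of 18 rose, 12 fell and 4 did not pass (median -0.20). The endoplasmic reticulum chaperone bip1 (-1.62) and the cytosolic mas5 (-1.51) were among the falls. Compared with all other genes, camera placed the stress regulators (adjusted p = 3.0e-07), the core stress response (9.0e-04) and the chaperones (0.0198) lower, with adjusted p = 0.306 with an estimated correlation for the stress regulator list, adjusted p = 0.311 with an estimated correlation for the core stress response list and adjusted p = 0.322 with an estimated correlation for the chaperone list. These groups moved with an index shift of 2.01. In the fit with the index, 13 of 38 stress regulators were lower (median -0.19) and 14 of 23 core stress genes (median -0.66), among them cta3 (-1.22) and ntp1 (-0.97). There srk1 stood at -0.75 and was past the threshold, while sck2 (-0.098), gpd1 (-0.26) and sty1 (0.52, with the sign changed) were not. The chaperones had a median of -0.076. In this fit bip1 (0.66) and mas5 (0.79) stood above 0, though both had fallen in wild type. In the deletion their means were also lower after treatment: 12.04 and 11.60 for bip1 and 10.91 and 10.61 for mas5 in control and treated arrays. Camera on that fit still called the stress regulator (adjusted p = 0.00253) and core stress response (adjusted p = 2.4e-07) lists in the same direction and no longer called the chaperone (adjusted p = 0.228) list (0.324 to 0.687 with an estimated correlation).

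All 11 measured members of the list of Pap1-dependent oxidative stress genes fell in wild type cells, with a median of -0.56. The ABC transporter bfr1 fell by 2.62-fold (-1.39 ± 0.04), followed by the glutathione transferase gst2 (-0.99 ± 0.15), catalase ctt1 (-0.72 ± 0.06), the flavoprotein obr1 (-0.72 ± 0.04) and sulfiredoxin srx1 (-0.56 ± 0.04). Smaller falls were seen for caf5 (-0.39), the peroxiredoxin tpx1 (-0.19), glutathione reductase pgr1 (-0.16) and thioredoxin reductase trr1 (-0.12), and pgr1 stood at 0.032 after quantile normalization over the S. pombe genes. In the wider antioxidant list 5 of 23 rose, 15 fell and 3 did not pass (median -0.26). The glutaredoxins grx3 (1.28) and grx4 (0.85) were among those that rose, while gst3 (-1.83) and the glutathione peroxidase gpx1 (-0.27) fell. Camera placed the Pap1-dependent genes lower than other genes (adjusted p = 0.00840, and adjusted p = 0.306 with an estimated correlation). The antioxidant list did not pass (0.129). The index shift was 2.01 in these arrays, and the fit with the index had 5 of 11 Pap1-dependent genes lower and 2 higher (median -0.11). There bfr1 stood at -1.81 and srx1 at -1.25. With the sign changed pgr1 stood at 0.45, past the threshold (adjusted p = 0.0312), and gst2 (0.74), caf5 (0.70) and trr1 (0.25) did not pass. The antioxidant median was 0.24 beside a mean of 0.059. Camera there no longer called the Pap1-dependent (adjusted p = 0.209) list (0.669 with an estimated correlation).

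Of the metal gene lists, only that of iron-sulfur and heme proteins passed camera in wild type cells (adjusted p = 0.0139, and adjusted p = 0.306 with an estimated correlation). The iron reductase frp1 rose by 2.37-fold (1.25 ± 0.06) and the transporter abc3 by 0.96. The regulator php4, which represses iron-using genes when iron is short, fell by 3.16-fold (-1.66 ± 0.07). In the iron acquisition list 4 of 13 rose, 7 fell and 2 did not pass (median -0.19). In the zinc and copper list 8 of 15 rose, 5 fell and 2 did not pass (median 0.12). The zinc transporters cis4 (1.25) and zhf1 (0.81), the zinc-repressed alcohol dehydrogenase adh4 (0.72) and metallothionein zym1 (0.42 ± 0.05) rose, and the copper chaperone ccs1 fell (-0.73). In the iron-sulfur and heme list 3 of 24 rose, 14 fell and 7 did not pass (median -0.52), with tim18, isa1, cyt1 and rip1 between -2.79 and -2.08. Camera did not call iron acquisition (0.550) or zinc and copper (0.505). The index shift in these arrays was 2.01. With the index as a covariate frp1 (0.91), cis4 (1.02) and adh4 (1.94) were higher and zym1 lower (-1.28). The medians there were 0.37 for iron acquisition, 0.35 for zinc and copper and 0.39 for iron-sulfur and heme proteins, and camera no longer called the iron-sulfur and heme (adjusted p = 0.0773) list (0.687 with an estimated correlation). The sign was changed for php4 (0.28), ccs1 (0.85), tim18 (0.45), cyt1 (0.58) and rip1 (0.91).

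Genes of carbon metabolism and respiration mostly fell in wild type cells. In the list of glycolysis, trehalose and glycerol 3 of 34 rose, 23 fell and 8 did not pass (median -0.52). They were led by the glycerol dehydrogenase gld1 (5.48-fold, -2.45 ± 0.05), the hexose transporters ght1 (-2.39, a lower bound in size, with a treated mean of 3.36 under background) and ght2 (-1.73), and fructose bisphosphatase fbp1 (-1.75). For respiration 12 of 43 rose, 25 fell and 6 did not pass (median -0.25), with idh1 at -1.63. In sulfur assimilation 1 of 14 rose, 9 fell and 4 did not pass (median -0.27), with met6 at -1.98, sam1 at -1.73 and pof1 at -1.76. Among amino acid biosynthesis genes 8 of 34 rose, 18 fell and 8 did not pass (median -0.18), with his5 up by 1.15 and ser2 at -1.45, lys7 at -1.10 and lys4 at -0.96. In the sterol list 10 of 30 rose, 18 fell and 2 did not pass (median -0.38), with erg25, sur2 and sre2 between -2.09 and -1.99 after erg31. For membrane and multidrug transporters 7 of 22 rose, 9 fell and 6 did not pass (median 0.037, mean -0.32), with vcx1 at -2.04 and abc2 at -1.67. Camera called carbohydrate (9.0e-04), respiration (0.0385) and sulfur (0.0172) genes lower, and not amino acid (0.118), sterol (0.110) or transporter (0.629) genes. The called lists had adjusted p = 0.306 with an estimated correlation for each. After quantile normalization the respiration (0.132) and sulfur (0.132) lists did not pass. The index shift was 2.01, and with the index as a covariate gld1 (-1.53) and ght2 (-1.06) were lower. The carbohydrate and respiration medians there were -0.063 and 0.0037. Above 0 stood sam1 (1.50), ser2 (0.86) and lys4 (0.84) and the amino acid (0.54), sulfur (0.28), sterol (0.42) and transporter (0.19) medians. Means in deletion control and treated arrays were 10.89 and 10.84 for sam1, 7.44 and 7.20 for ser2 and 11.63 and 11.60 for lys4. These genes thus rose in neither strain. Other genes with the sign changed were ght1 (0.38), idh1 (0.70), met6 (0.24), pof1 (0.10), lys7 (0.59), erg25 (0.74), sur2 (0.51), sre2 (0.13), vcx1 (0.98) and abc2 (0.68). Camera in this fit no longer called the carbohydrate (adjusted p = 0.103), respiration (adjusted p = 0.587) and sulfur (adjusted p = 0.0511) lists (0.669 to 0.819 with an estimated correlation). It called the amino acid (adjusted p = 2.4e-07, 0.669 with an estimated correlation, higher) and sterol (adjusted p = 0.00785, 0.669 with an estimated correlation, higher) lists there.

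The G2/M, cell separation, histone and proteasome lists lay lower than other genes in wild type cells by camera, and ribosomal proteins lay higher (adjusted p of these lists 0.306 to 0.436 with an estimated correlation). After quantile normalization ribosomal proteins (0.509) and histones (0.0566) did not pass. In the G2/M list 4 of 25 rose, 19 fell and 2 did not pass (median -0.57). The falls included the inhibitory kinase wee1 (-1.86 ± 0.05), the CDK inhibitor rum1 (-1.37) and, less, the phosphatase cdc25 (-0.46 ± 0.09). Of the cell separation genes 1 of 12 rose, 9 fell and 2 did not pass (median -0.71), with the glucan synthases ags1 at -1.86 and bgs4 at -1.55. Of the histones 0 of 10 rose, 7 fell and 3 did not pass (median -0.45), htb1 most (7.36-fold, -2.88 ± 0.05). Of the proteasome genes 3 of 33 rose, 20 fell and 10 did not pass (median -0.35), with rpt5 at -2.35. Ribosomal protein genes rose in 54 of 119 cases and fell in 9, 56 did not pass, and the median was 0.097. The genes rpl4101 (0.90) and rps2202 (0.78) led them. In ribosome biogenesis 23 of 52 rose, 17 fell and 12 did not pass (median 0.11), with rrp6 up (1.45) and gar2 down (-1.45). For MBF targets and replication 9 of 30 rose, 15 fell and 6 did not pass (median -0.21), with mcm7 at 1.31 and cdt2 at -1.86. For DNA repair 15 of 30 rose, 10 fell and 5 did not pass (median 0.052), with rad16 at 1.23 and uvi15 at -1.88. For mating and meiosis 15 of 36 rose, 12 fell and 9 did not pass (median -0.037, and above 0 after centring or quantile normalization), with mfm2 at 1.66 and ste13 at -1.71. Camera called G2/M (0.0119), cell separation (0.0153), histone (0.0165) and proteasome (0.00257) genes lower and ribosomal proteins higher (0.0145). These had adjusted p = 0.436 with an estimated correlation for the G2/M list and adjusted p = 0.306 with an estimated correlation for the cell separation, histone, proteasome and ribosomal protein lists. The ribosome biogenesis (0.464), MBF (0.331), DNA repair (0.507) and mating (0.981) lists did not pass. The index shift was 2.01, and in the fit with the index the medians were 0.17 for G2/M, 0.39 for cell separation, 0.22 for histones, 0.080 for proteasome, -0.035 for ribosomal proteins, 0.22 for ribosome biogenesis, 0.12 for MBF, -0.0054 for DNA repair and 0.23 for mating genes. Camera then called the cell separation (adjusted p = 0.0264) list in the opposite direction and no longer called the G2/M (adjusted p = 0.561), histone (adjusted p = 0.622), proteasome (adjusted p = 0.931) and ribosomal protein (adjusted p = 0.103) lists (0.669 to 0.976 with an estimated correlation). Signs were changed for ags1 (0.48), bgs4 (0.38), cdc25 (0.11), rpt5 (0.58), rpl4101 (-0.10), rrp6 (-0.45), gar2 (1.18) and cdt2 (0.84).

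Counts adjusted over the list alone were equal to those over all genes in wild type cells except for the lists ribosomal protein (51 and 8 beside 54 and 9), MBF and replication (9 and 16 beside 9 and 15), G2/M (4 and 20 beside 4 and 19) and respiration (13 and 25 beside 12 and 25), given as rose and fell. Median, mean and test differed in sign for mating and meiosis (median -0.037, mean -0.029, test higher) and transporter (median 0.037, mean -0.32, test lower). Of the 10 genes listed for removal of nitric oxide and S-nitrosoglutathione only pgr1, trr1 and trx1 were measured, too few to test.

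The same treatment in cells without pap1 asked which responses go on when Pap1 is absent. Stress factors fell here too: atf1 fell by 3.00-fold (log2 -1.59 ± 0.08, SE, n = 2 per group, adjusted p = 7.6e-06) and its partner pcr1 by a log2 change of -1.63 ± 0.06. The factor atf21 fell to a treated mean of 3.39, under the background level of 3.41, so that its change of -2.25 is a lower bound in size. The gene sfp1 fell by an amount between those of atf21 and gld1. The glycerol dehydrogenase gld1 (-1.96 ± 0.05), the cAMP phosphodiesterase cgs2 (-1.62 ± 0.08) and mug108 (-1.95 ± 0.04) were among the larger falls, with nep2, rds1, psy1 and tbp1 between -1.85 and -1.77. The largest rises were in ssm4 (1.88, a lower bound, with a control mean of 3.06 under background), the copper transporter ctr4 (2.80-fold, 1.49 ± 0.07), mfm2 (1.44) and the zinc-repressed alcohol dehydrogenase adh4 (2.59-fold, 1.37 ± 0.06). Glutamine synthetase gln1, adenine deaminase dea2, the thiamine-repressible phosphatase pho4, the glutaredoxin grx4, the zinc transporter cis4 and the ferric reductase frp1 followed, from 1.24 down to 1.09. In limma 1028 genes rose and 778 fell, with 17 and 68 of them changing by at least 2-fold. The split was 1047 and 778 with centred arrays, and 1043 and 816 after quantile normalization. The index was 0.99 higher in the treated arrays of this strain. With it as a covariate the common effects were -1.53 for gld1, -1.32 for cgs2, -1.89 for mug108, 2.41 for ctr4, 1.94 for adh4, 2.32 for gln1 and 1.39 for dea2, each past the threshold.

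Among stress genes of the deletion strain 29 of 38 stress regulators fell and 2 rose (median -0.39), including the regulatory subunit of protein kinase A, cgs1 (-1.62 ± 0.06). Of the core stress response 19 of 23 fell and 1 rose (median -0.61), with srk1 (-1.55 ± 0.04), cta3 (-1.54 ± 0.05) and ntp1 (-1.09 ± 0.04). Chaperones fell in 8 of 18 cases and rose in 0 (median -0.11), with the heat shock factor hsf1 at -0.91. Of the Pap1-dependent genes 2 of 11 rose, 6 fell and 3 did not pass (median -0.27). In this group bfr1 fell by 3.06-fold (-1.61 ± 0.04), srx1 by 1.89-fold (-0.92 ± 0.04), while obr1 (-0.61) and ctt1 (-0.61) fell less and trr1 (0.083) and caf5 (0.16) did not pass. Glutathione reductase pgr1 rose (0.17 ± 0.04) and tpx1 (-0.27 ± 0.04) fell. Of the other genes named in each comparison, gpd1 (-0.84 ± 0.05), gpx1 (-0.54 ± 0.04), zym1 (-0.46 ± 0.05), hsp9 (-0.41 ± 0.04), sty1 (-0.29 ± 0.06) and hsp16 (-0.25 ± 0.04) fell and cdc25 (-0.14 ± 0.09) did not pass. In the antioxidant list 6 of 23 rose, 6 fell and 11 did not pass (median 0.0056), with grx4 up and superoxide dismutase sod1 down (-0.83 ± 0.04). For carbohydrate genes 4 of 34 rose, 18 fell and 12 did not pass (median -0.19), with ght2 at -1.36. For transporters 6 of 22 rose, 8 fell and 8 did not pass (median 0.045), with car1 at 0.68. Camera placed the stress regulators (adjusted p = 5.1e-09), core stress response (3.6e-08), chaperones (0.00658) and carbohydrate genes (3.1e-04) lower. These had adjusted p = 0.250 with an estimated correlation for the stress regulator, core stress response and carbohydrate lists and adjusted p = 0.306 with an estimated correlation for the chaperone list. The Pap1-dependent (0.0764), antioxidant (0.638) and transporter (0.678) lists did not pass. The index shift in these arrays was 0.99. For the common effect with the index camera still called the stress regulator (median -0.19, adjusted p = 0.00253) and core stress response (median -0.66, adjusted p = 2.4e-07) lists in the same direction and no longer called the chaperone (median -0.076, adjusted p = 0.228) and carbohydrate (median -0.063, adjusted p = 0.103) lists (0.324 to 0.687 with an estimated correlation). There sty1 (0.52) and cdc25 (0.11) had the opposite sign.

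Among iron acquisition genes of the deletion strain 5 of 13 rose, 4 fell and 4 did not pass (median 0.13), with the siderophore transporter str1 up by 2.10-fold (1.07 ± 0.08) and php4 lower (-0.66). In the zinc and copper list 8 of 15 rose, 4 fell and 3 did not pass (median 0.15). In the iron-sulfur and heme list 6 of 24 rose, 11 fell and 7 did not pass (median -0.053). In respiration 4 of 43 rose, 19 fell and 20 did not pass (median -0.085), and tim18, a member of both lists, fell by 2.16-fold. Amino acid genes rose in 21 of 34 cases and fell in 3 (median 0.17), with his5 (0.88), his4 (0.56) and arg5 (0.53) after gln1 (1.24). Ribosome biogenesis genes rose in 30 of 52 and fell in 7 (median 0.21), nop9 most (0.89), and of 119 ribosomal protein genes 17 rose and 1 fell (median 0.026). For sulfur 3 of 14 rose, 3 fell and 8 did not pass (median 0.038), and for sterols 13 of 30 rose, 9 fell and 8 did not pass (median 0.067). For MBF and replication 9 of 30 rose, 10 fell and 11 did not pass (median 0.060), with res2 at -1.12. For histones 1 of 10 rose, 5 fell and 4 did not pass (median -0.22), with htb1 at -1.08. In the G2/M list 2 of 25 rose, 9 fell and 14 did not pass (median -0.14), with wee1 at -1.05. In cell separation 5 of 12 rose, 6 fell and 1 did not pass (median -0.24), and in DNA repair 8 of 30 rose, 7 fell and 15 did not pass (median 0.031), with rad50 at -1.07. In the proteasome list 1 of 33 rose, 14 fell and 18 did not pass (median -0.11) and in mating and meiosis 17 of 36 rose, 8 fell and 11 did not pass (median 0.19). Camera called respiration (0.00277), proteasome (0.00277), G2/M (0.0198) and histone (0.0228) genes lower and amino acid (0.0198) and ribosome biogenesis (0.0198) genes higher. These lists had adjusted p = 0.250 with an estimated correlation for the respiration and histone lists, adjusted p = 0.306 with an estimated correlation for the proteasome, amino acid and ribosome biogenesis lists and adjusted p = 0.581 with an estimated correlation for the G2/M list. The index shift here was 0.99. With the index as a covariate 22 amino acid and 16 ribosome biogenesis genes were higher. Camera on the common effect still called the amino acid (median 0.54, adjusted p = 2.4e-07) list in the same direction and no longer called the respiration (median 0.0037, adjusted p = 0.587), proteasome (median 0.080, adjusted p = 0.931), G2/M (median 0.17, adjusted p = 0.561), histone (median 0.22, adjusted p = 0.622) and ribosome biogenesis (median 0.22, adjusted p = 0.0570) lists (0.669 to 0.976 with an estimated correlation). Opposite signs were found for php4 (0.28), tim18 (0.45) and htb1 (0.54). Lists called only in that fit were cell separation (adjusted p = 0.0264, 0.669 with an estimated correlation, higher) and sterol (adjusted p = 0.00785, 0.669 with an estimated correlation, higher). In the deletion strain the other lists, from iron acquisition to mating, did not pass, with adjusted p from 0.0945 to 0.874.

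Counts adjusted over the list alone were equal to those over all genes in the deletion strain except for the lists ribosomal protein (9 and 1 beside 17 and 1), ribosome biogenesis (31 and 8 beside 30 and 7), G2/M (2 and 7 beside 2 and 9) and proteasome (0 and 13 beside 1 and 14). Median, mean and test differed in sign for antioxidant (median 0.0056, mean -0.069, test lower), sulfur (median 0.038, mean -0.080, test lower), MBF and replication (median 0.060, mean -0.026, test lower), DNA repair (median 0.031, mean -0.0093, test lower), sterol (median 0.067, mean -0.022, test higher) and transporter (median 0.045, mean -0.10, test lower).

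**Figure D3:**
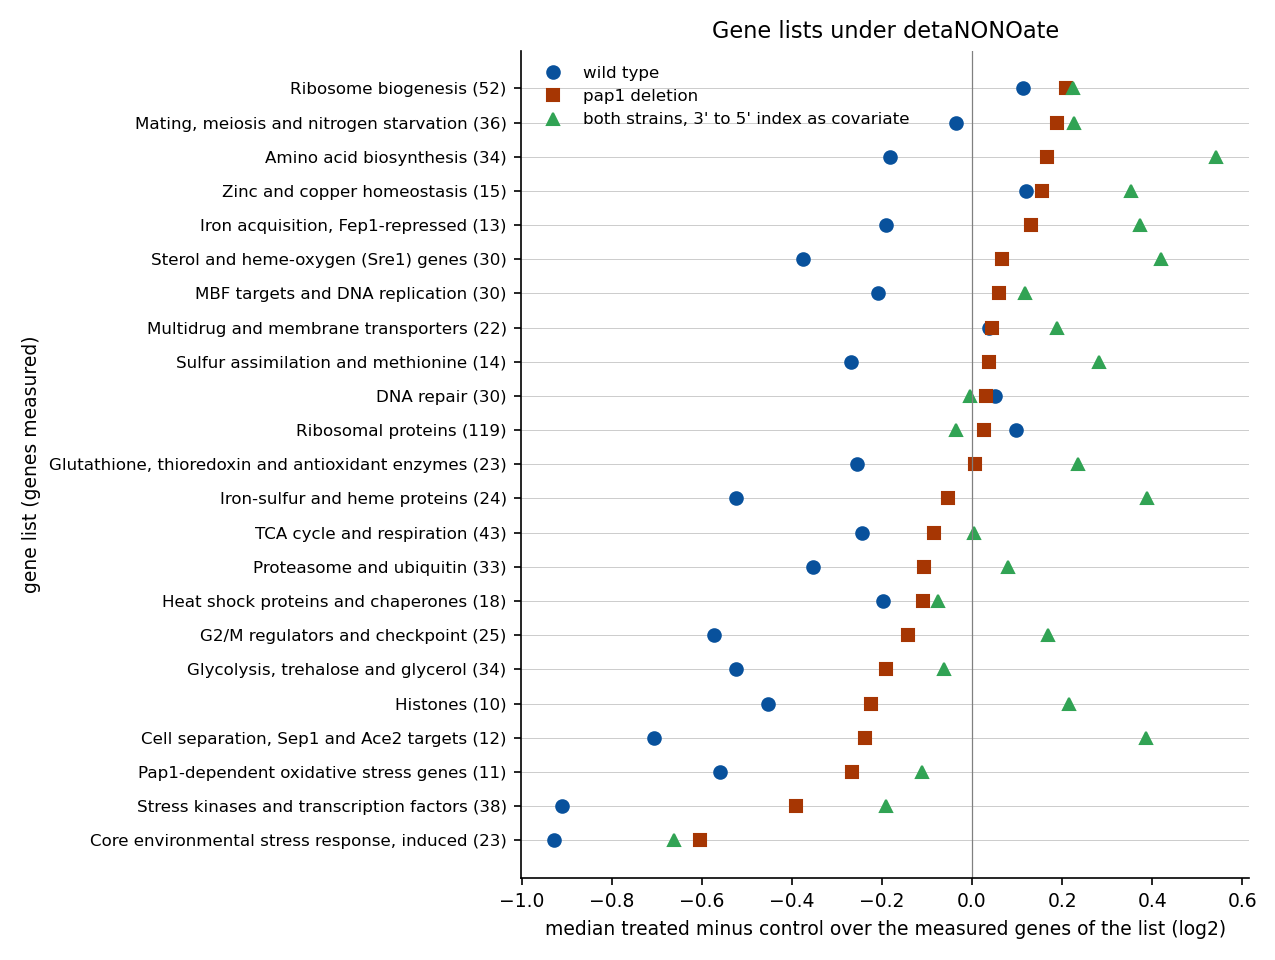
The median log2 change of each of the 23 gene lists under detaNONOate is plotted for wild type cells, for the pap1 deletion and for the common effect with the 3' to 5' index as a covariate. The core stress response lies at -0.93, -0.61 and -0.66, and amino acid biosynthesis at -0.18, 0.17 and 0.54.

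The interaction between treatment and strain asked which responses to nitric oxide differed when pap1 was missing. It is the change in the deletion minus the change in wild type. The changes of atf1 (0.13 ± 0.11, adjusted p = 0.326), ntp1 (0.13 ± 0.06), ctt1 (0.11 ± 0.08), obr1 (0.11 ± 0.06), hsp16 (-0.067 ± 0.06), tpx1 (-0.079 ± 0.06) and cdc25 (0.31 ± 0.13) did not pass this test. Those of the kinase sty1 (0.92 ± 0.08, adjusted p = 1.1e-04) and of gpd1 (0.66 ± 0.07) passed, and both genes fell less in the deletion. So did those of trr1 (0.21 ± 0.06), caf5 (0.55 ± 0.19, adjusted p = 0.0421) and pgr1 (0.33 ± 0.06), which fell in wild type, while in the deletion pgr1 rose and the others did not pass. The gene zym1 rose in wild type and fell in the deletion (-0.88 ± 0.06). Sulfiredoxin srx1 (-0.36 ± 0.06), gpx1 (-0.27 ± 0.06) and hsp9 (-0.18 ± 0.05) fell more in the deletion. The largest positive differences were in erg31 (2.22 ± 0.13), the helicase sum3 (2.02 ± 0.12), pfa3 (2.02), esc1 (1.96) and coq10 (1.90), all of which fell in wild type and had lower treated than control means in the deletion too. The largest negative ones were in the splicing factor snu66 (-1.43 ± 0.09), bqt1 (-1.22), epr1 (-1.21), the mismatch repair gene pms1 (-1.19) and dmc1 (-1.18). In limma 1711 genes passed, 983 with a positive and 728 with a negative difference (57.5% positive). The split was 845 and 940 (47.3%) with arrays centred on the median S. pombe gene, and 810 and 975 (45.4%) after quantile normalization. Of the 1711 genes, 1564 had changed in wild type, and in 1506 the difference was opposite in sign to the wild type change. The difference subtracts the wild type change and shares its arrays, so an opposite sign is partly built in. The index shift differed between strains by 1.02.

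The responses of the strains were alike in direction and unlike in size. Across the 2896 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.79 and a Spearman correlation of 0.76, and the slope of the deletion change on the wild type change was 0.43. The ratio of the index shifts, deletion over wild type, was 0.49, with 0.27 to 0.75 over the control transcripts. In both strains 794 genes rose, where chance overlap would give 417, and 657 fell, where chance would give 309. Another 49 rose in wild type and fell in the deletion, and 88 did the opposite. Of the 1451 genes that changed the same way in both strains, 80.0% changed more in wild type.

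**Figure D4:**
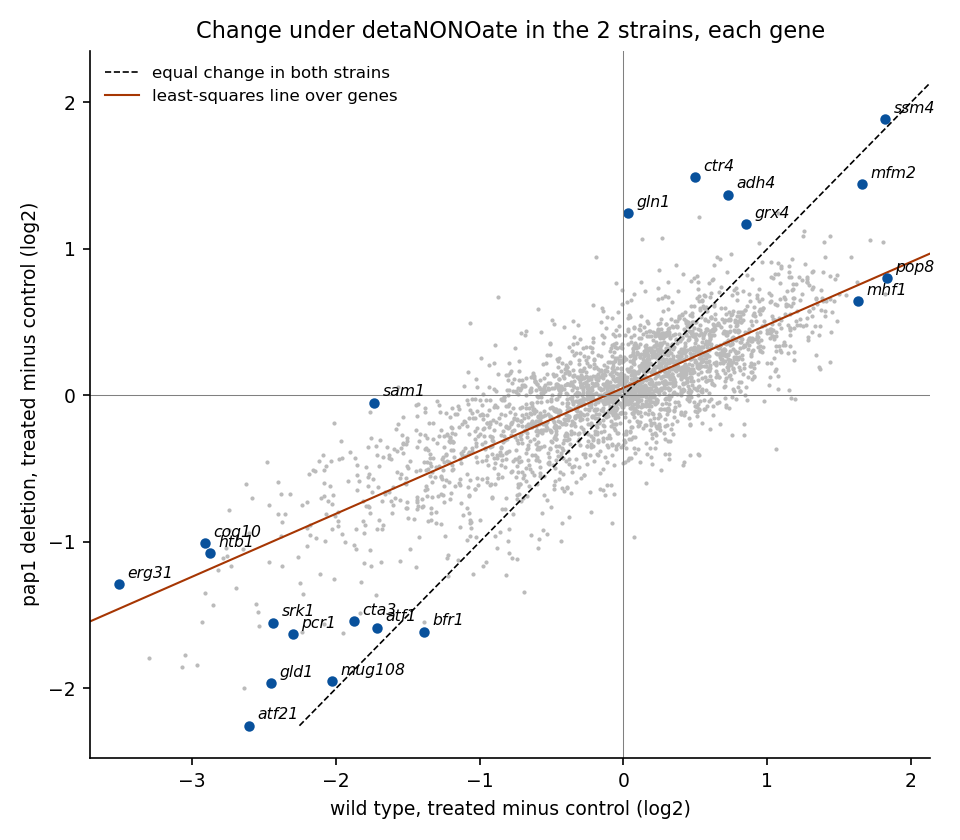
Each point is a gene, with its log2 change under detaNONOate in wild type on the horizontal axis and in the pap1 deletion on the vertical axis; a line marks the slope of 0.43. Stress factor atf1 lies at -1.71 and -1.59, and erg31 at -3.51 and -1.29.

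The gene lists that passed camera in the interaction had positive median differences, except the ribosomal proteins, and with an estimated correlation the adjusted p of these lists was 0.344 to 0.453. The difference was positive for 10 of 12 cell separation genes and negative for 0 (median 0.84), among them ags1 (1.21) and adg1 (1.13). The same sign was found for 10 of 14 sulfur genes (median 0.31), with sam1 (1.69), and for 17 of 30 sterol genes against 1 (median 0.40). It was positive for 16 of 24 iron-sulfur and heme genes (median 0.38), with tim18 (1.68) and rip1 (1.57), and for 22 of 34 amino acid genes (median 0.40), with ser2 (1.21) and gln1 (1.21). It was also positive for 24 of 38 stress regulators (median 0.34) and for 18 of 33 proteasome genes (median 0.24), with rpt5 (1.54). Ribosomal proteins went the other way, 7 positive and 24 negative of 119 (median -0.091). Of the Pap1-dependent genes 6 of 11 had a positive and 2 a negative difference (median 0.21), with trx2 at 0.66. Of the core stress genes 9 and 7 of 23 did (median 0.13), and neither list passed camera (0.528 and 0.694). Camera adjusted p was 0.00288 for cell separation, 0.00468 for sulfur, 0.00565 for sterol, 0.00288 for iron-sulfur, 9.8e-04 for amino acid, 0.00373 for stress regulator, 0.0376 for proteasome and 0.00468 for ribosomal protein genes. These gave adjusted p = 0.344 with an estimated correlation for the iron-sulfur and heme, sulfur, amino acid and cell separation lists, adjusted p = 0.361 with an estimated correlation for the ribosomal protein list and adjusted p = 0.453 with an estimated correlation for the proteasome, sterol and stress regulator lists. The proteasome list did not pass with centred arrays (0.0620) or after quantile normalization (0.222), nor did ribosomal proteins after quantile normalization (0.647). The remaining lists did not pass, and among them carbohydrate (0.0501), histone (0.0501) and G2/M (0.0632) genes came closest, of which G2/M (0.0465) and carbohydrate (0.0383) passed after quantile normalization. Counts adjusted over the list alone, as positive and negative, differed only for core stress response (10 and 7 beside 9 and 7), amino acid (23 and 1 beside 22 and 1), ribosomal protein (5 and 17 beside 7 and 24), MBF and replication (13 and 6 beside 12 and 5), DNA repair (8 and 13 beside 7 and 13), respiration (23 and 11 beside 23 and 10) and stress regulator (25 and 4 beside 24 and 3). The shift of the index differed between strains by 1.02 in the same arrays.

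The comparison of the control strains, both given decomposed detaNONOate, asked what the loss of pap1 changed without active donor. Next to pap1 itself (-7.58, a lower bound in size, with a signal under background in the deletion), the glutathione transferase gst2 was 17.7-fold lower in the deletion (log2 -4.15 ± 0.15, SE, n = 2 per group, adjusted p = 1.3e-05), the pyridoxal reductase plr1 5.64-fold lower (-2.50 ± 0.05) and the flavoprotein obr1 3.24-fold lower (-1.70 ± 0.04), followed by sap1 (-0.98 ± 0.08). Smaller falls were seen in glucose-6-phosphate dehydrogenase zwf1 (-0.48 ± 0.06), thioredoxin trx2 (-0.37 ± 0.04), srx1 (-0.19 ± 0.04) and zym1 (-0.23 ± 0.05). Catalase ctt1 (-0.17 ± 0.06, adjusted p = 0.0829), trr1 (-0.13 ± 0.04), tpx1 (-0.030 ± 0.04), pgr1 (-0.036 ± 0.04), gpx1 (-0.021 ± 0.04), caf5 (0.042 ± 0.14), atf1 (-0.22 ± 0.08), sty1 (-0.17 ± 0.06), ntp1 (-0.13 ± 0.04), gpd1 (-0.097 ± 0.05), hsp9 (0.055 ± 0.04), hsp16 (-0.032 ± 0.04) and cdc25 (0.33 ± 0.09) did not pass. The largest rises were in the anaphase activator slp1 (0.94 ± 0.05), atg12 (0.67 ± 0.06), the glucanase exg1 (0.64 ± 0.05) and urg2 (0.55 ± 0.07), after tlh2 (1.31 ± 0.09), a subtelomeric helicase with near-identical copies whose value is uncertain. In limma 238 genes were higher and 265 lower in the deletion (47.3% higher), and 335 and 249 (57.4% higher) with arrays centred on the median S. pombe gene. The total of 503 depended on single arrays: it was 108 without wild type control replicate 1, 127 without replicate 2, 113 without pap1 deletion control replicate 1 and 135 without its replicate 2. The index was 0.31 higher in the deletion control arrays. The strain effect common to treated and control arrays with the index as a covariate was -3.84 for gst2, -2.29 for plr1, -1.66 for obr1, -0.38 for zwf1, 0.89 for slp1 and 0.72 for exg1. The sign was opposite for pgr1 (0.070), gpd1 (0.11) and sty1 (0.13).

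Pap1-dependent genes as a group were lower in the control deletion arrays by camera (adjusted p = 7.0e-06, and adjusted p = 0.301 with an estimated correlation). Of the 11 measured members 6 fell, 0 rose, and the median was -0.19 beside a mean of -0.68. In the antioxidant list 6 of 23 fell (median -0.11), with gcs1 (-0.29). Of the stress regulators 12 of 38 fell (median -0.17), with the phosphorelay gene mpr1 (-0.79 ± 0.07) and cgs1 (-0.77 ± 0.06). Of the core stress genes 5 of 23 fell (median -0.070), with cta3 (-0.38). Of the iron-sulfur and heme genes 7 fell and 1 rose of 24 (median -0.098), with isa1 (-0.73), and of iron acquisition genes 3 of 13 fell (median -0.12). Ribosomal proteins rose in 4 of 119 cases (median 0.037). Camera gave adjusted p = 7.0e-06 for Pap1-dependent, 4.8e-06 for stress regulator, 0.00431 for antioxidant, 0.0103 for core stress, 0.00743 for iron-sulfur, 0.0398 for iron acquisition and 0.00743 for ribosomal protein genes, the last 0.517 after quantile normalization. These gave adjusted p = 0.301 with an estimated correlation for the Pap1-dependent and antioxidant lists, adjusted p = 0.609 with an estimated correlation for the core stress response and iron acquisition lists, adjusted p = 0.451 with an estimated correlation for the iron-sulfur and heme and stress regulator lists and adjusted p = 0.460 with an estimated correlation for the ribosomal protein list. The other lists did not pass, with adjusted p from 0.185 upward. Counts adjusted over the list alone, as rose and fell, differed for Pap1-dependent (0 and 8 beside 0 and 6), antioxidant (0 and 10 beside 0 and 6), iron acquisition (0 and 4 beside 0 and 3), iron-sulfur and heme (3 and 8 beside 1 and 7), ribosomal protein (0 and 0 beside 4 and 0), ribosome biogenesis (0 and 0 beside 3 and 3), MBF and replication (5 and 3 beside 5 and 2), G2/M (3 and 2 beside 2 and 2), DNA repair (1 and 1 beside 1 and 2), mating and meiosis (2 and 2 beside 3 and 2), sterol (2 and 7 beside 2 and 5), stress regulator (1 and 19 beside 0 and 12) and transporter (5 and 8 beside 2 and 6). The index shift was 0.31. For the common strain effect with the index camera still called the Pap1-dependent (median -0.16, adjusted p = 6.1e-05), core stress response (median -0.052, adjusted p = 0.0143), antioxidant (median -0.064, adjusted p = 0.00194) and stress regulator (median -0.055, adjusted p = 0.0160) lists in the same direction and no longer called the iron acquisition (median -0.077, adjusted p = 0.238), iron-sulfur and heme (median 0.064, adjusted p = 0.745) and ribosomal protein (median 0.019, adjusted p = 0.666) lists (0.253 to 0.912 with an estimated correlation). Only in that fit did camera call the amino acid (adjusted p = 2.8e-04, 0.702 with an estimated correlation, higher) and cell separation (adjusted p = 0.00131, 0.702 with an estimated correlation, higher) lists. There 6 of 11 Pap1-dependent genes were lower and 0 higher, as were 12 and 4 stress regulators, 3 and 7 iron-sulfur and heme genes and 0 and 1 iron acquisition genes.

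The comparison of the strains after treatment asked which transcript levels differed once both had met nitric oxide. Beside pap1 (-7.94, again a lower bound in size), gst2 was 9.10-fold lower in the deletion (log2 -3.19 ± 0.15, SE, n = 2 per group, adjusted p = 5.8e-06), plr1 3.60-fold lower (-1.85 ± 0.05), obr1 3.00-fold lower (-1.59 ± 0.04) and the meiotic recombinase dmc1 2.80-fold lower (-1.49 ± 0.07). Metallothionein zym1 (-1.10 ± 0.05), srx1 (-0.55 ± 0.04), gpx1 (-0.29 ± 0.04), hsp9 (-0.12 ± 0.04) and tpx1 (-0.11 ± 0.04) were also lower. Higher in the deletion were qcr1 of respiratory complex III (1.83 ± 0.07), sum3 (1.81 ± 0.08), esc1 (1.72 ± 0.16), S-adenosylmethionine synthetase sam1 (1.70 ± 0.04), gda1 (1.61 ± 0.16), sty1 (0.76 ± 0.06), cdc25 (0.64 ± 0.09), caf5 (0.60 ± 0.14), gpd1 (0.56 ± 0.05) and pgr1 (0.30 ± 0.04). The levels of atf1 (-0.088 ± 0.08, adjusted p = 0.331), ctt1 (-0.056 ± 0.06), hsp16 (-0.099 ± 0.04), ntp1 (0.0042 ± 0.04) and trr1 (0.073 ± 0.04) did not pass the threshold. In limma 1139 genes were higher and 766 lower in the treated deletion (59.8% higher), and 913 and 1020 (47.2% higher) after quantile normalization. The index was 3.35 in the treated wild type and 2.64 in the treated deletion arrays. The common strain effect with the index was 0.53 for qcr1, 0.42 for sum3, 0.54 for sam1, 0.13 for sty1, -0.50 for zym1 and -0.67 for dmc1, and trr1 (-0.066), hsp9 (0.00015) and ntp1 (-0.086) had the opposite sign.

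As groups, amino acid genes were higher in the treated deletion in 27 of 34 cases (median 0.37) and cell separation genes in 11 of 12 (median 0.92), with adg1 at 1.19. Sulfur genes were higher in 11 of 14 (median 0.29) and iron-sulfur and heme genes in 16 of 24 against 2 lower (median 0.31), with bio2 at 1.32. Sterol genes were higher in 21 of 30 against 1 (median 0.31). Ribosomal proteins had 19 higher and 26 lower of 119 (median -0.044), and the Pap1-dependent list 3 higher and 6 lower of 11 (median -0.11, camera 0.134). Camera adjusted p was 7.3e-05 for amino acid, 0.00172 for cell separation, 0.0105 for sulfur, 0.0105 for iron-sulfur, 0.00480 for sterol and 0.0472 for ribosomal protein genes, the last 0.698 after quantile normalization. These gave adjusted p = 0.386 with an estimated correlation for the iron-sulfur and heme, sulfur, amino acid and cell separation lists, adjusted p = 0.532 with an estimated correlation for the ribosomal protein list and adjusted p = 0.495 with an estimated correlation for the sterol list. Counts adjusted over the list alone differed for antioxidant (8 and 9 beside 8 and 8), ribosomal protein (8 and 7 beside 19 and 26), ribosome biogenesis (21 and 9 beside 22 and 9) and proteasome (17 and 3 beside 18 and 3), and median, mean and test differed in sign for DNA repair (median 0.076, mean -0.075, test lower) and transporter (median -0.010, mean 0.13, test lower). The other lists did not pass, with adjusted p from 0.0556 upward, and G2/M passed with centred arrays (0.0466). Camera on the common strain effect with the index still called the amino acid (median 0.14, adjusted p = 2.8e-04) and cell separation (median 0.23, adjusted p = 0.00131) lists in the same direction and no longer called the iron-sulfur and heme (median 0.064, adjusted p = 0.745), sulfur (median 0.12, adjusted p = 0.238), ribosomal protein (median 0.019, adjusted p = 0.666) and sterol (median 0.078, adjusted p = 0.166) lists (0.702 to 0.912 with an estimated correlation). The Pap1-dependent (adjusted p = 6.1e-05, 0.253 with an estimated correlation, lower), core stress response (adjusted p = 0.0143, 0.702 with an estimated correlation, lower), antioxidant (adjusted p = 0.00194, 0.253 with an estimated correlation, lower) and stress regulator (adjusted p = 0.0160, 0.702 with an estimated correlation, lower) lists were called in that fit and not between treated strains.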

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

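The 6 tests weighed in this part were chosen after the results were seen, as was the fit with the 3' to 5' index.

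Treatment changed more genes, and by more, in wild type than in the pap1 deletion: 1711 genes passed the test of the interaction, and the slope of the deletion change on the wild type change was 0.43 ± 0.0062 (SE over genes, which are not independent). In control probe sets outside the comparisons, the 3' to 5' index had shifted by 2.01 in treated wild type and by 0.99 in treated deletion arrays, a difference of 1.02. These probe sets are of S. pombe transcripts, mainly RIP1 in the median, whose own levels can change with treatment. Shortening of transcripts only before the added control RNAs were mixed in was argued against by the added dap RNA, whose 3' to middle difference shifted by 1.22 in treated wild type arrays, more than 2 times its replicate spread of 0.11. Shorter labelled targets stay open as an explanation, since the slope lay within the range of 0.27 to 0.75 that the shift ratios of the control transcripts gave, a value that could have fallen outside. A weaker response without Pap1, the biological explanation that the design gives, also stays open and was not tested apart from the index.

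The lists of the core stress response, the stress regulators and the chaperones were lower in treated arrays of both strains. As the whole cause, shorter labelled targets would leave no more members of a list lower than chance once the index is a covariate. This holds only if their effect has the same ratio between strains in each gene as in the index. For the core stress response 14 of 23 members were then lower past the threshold and 2 higher, where 2.46 lower would be expected by chance (exact hypergeometric p = 6.6e-09, with genes taken as independent), and for the stress regulators 13 of 38 were lower and 5 higher, against 4.07 (exact hypergeometric p = 8.5e-05). Both counts were made with the median index, whose shift had a ratio of 0.49, deletion over wild type. Single control transcripts had ratios of 0.27 to 0.75, and a shortened gene with a ratio above 0.49 could stay lower in this fit. With SRB4 alone as the index 12 of 2896 genes were lower with treatment. SRB4 shifted by 1.06 in wild type and 0.79 in the deletion, so little of it is left beside 1 treatment and 1 strain effect. A low count there can reflect lost precision, and nothing is drawn from it. Because of the range of ratios, the counts with the median index do not decide whether shorter labelled targets are the whole cause. This stays open for both lists, with sty1 (0.52) among their members, and for the chaperones, with 4 of 18 lower and 3 higher against 1.93 (exact hypergeometric p = 0.118). The medians were -0.66 ± 0.15 (bootstrap SE over genes, 5 members above and 18 below 0) for the core stress response, -0.19 ± 0.10 (12 and 26) for the stress regulators and -0.076 ± 0.080 (8 and 10) for the chaperones. Only the first lay more than 2 errors below 0. Camera with the index gave adjusted p = 2.4e-07, 0.00253 and 0.228, and 0.324 to 0.687 with an estimated correlation. An effect of nitric oxide on these genes is a hypothesis from the same data, and other technical differences between treated and control arrays, such as the hybridization controls at 8.37 and 9.49 in control and treated wild type and 8.30 and 8.41 in control and treated deletion arrays, were not tested as causes.

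Pap1-dependent genes were lower in control cells of the deletion, which received decomposed donor. The fit with the index gives 1 strain effect over treated and control arrays together. In it 6 of 11 members were lower past the threshold and 0 higher, where 0.957 lower would be expected by chance (exact hypergeometric p = 1.3e-04, with genes taken as independent). This argues against shorter labelled targets, as the median index measures them, as the whole cause. With single control transcripts as the index 6 (SRB4) to 727 (TFIID) of all genes were lower by strain, and list members were not counted there. The SRB4 fit has little precision. The median was -0.19 between control arrays. For the strain effect of that fit, which includes treated arrays, it was -0.16 ± 0.16 (bootstrap SE over genes, 2 members above and 9 below 0), within 2 errors of 0. Camera on that effect gave adjusted p = 6.1e-05 (adjusted p = 0.253 with an estimated correlation). Whether shorter targets account for the members not lower in that fit stays open. A wrong sample label was not seen, since pap1 was under background in each of the 4 deletion arrays. Loss of activation by Pap1 is the biological explanation that the design gives and stays a hypothesis.

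The test of the interaction also singled out genes and lists whose treatment effects differed between strains. Positive differences, in genes whose means were lower after treatment in both strains, were 2.22 for erg31, 2.02 for sum3, 2.02 for pfa3, 1.96 for esc1 and 1.90 for coq10. Negative ones were -1.43 for snu66, -1.22 for bqt1, -1.21 for epr1, -1.19 for pms1 and -1.18 for dmc1. The lists that passed camera at the preset correlation, none of which passed with an estimated one (adjusted p from 0.344 to 0.453), had median differences of 0.38 for iron-sulfur and heme proteins, 0.31 for sulfur assimilation, 0.40 for amino acid biosynthesis, -0.091 for ribosomal proteins, 0.84 for cell separation, 0.24 for the proteasome, 0.40 for sterol genes and 0.34 for stress regulators. The proteasome list did not pass with centred arrays (0.0620) or after quantile normalization (0.222), nor ribosomal proteins after quantile normalization (0.647). In data outside the comparisons, a probe set for a reporter sequence read 11.32 in deletion control arrays and 2.07 in wild type control arrays. Among probe sets with no gene name, 1895 changed under treatment in wild type. Among S. cerevisiae probe sets 293 passed the same test.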

How the results depend on the processing

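The index as a covariate, the fit without the treated wild type arrays, crossed replicate numbers and quantile normalization for the gene lists were chosen after the data were seen; where not said, the cause of a change was not tested. Signal over background limited the genes outside the 2812 that lay above the background level. Of 260 values given for named genes, 252 kept direction and side of the threshold with centred arrays, 246 after quantile normalization, 249 with trend and robust variance and 257 with a replicate block. In the fit with the index, which has no interaction, 131 stayed, 36 no longer passed, 1 newly passed and 56 changed sign. With 1 array left out, where the lone array is assumed to vary like the other groups, 2012 values stayed, 54 no longer passed, 9 newly passed and 5 changed sign. A 2-fold minimum left 519 genes in wild type, 85 in the deletion, 190 in the interaction, 5 between control strains and 132 between treated strains, by its own construction. The control strain count of 503 became 774 with trend and robust variance, 787 with only its groups in the fit, 905 with array weights and 62 with all probe sets tested. With the index as a covariate 821 genes passed for treatment, for either strain, and 696 for strain, and 5 lists moved with treatment. With single control transcripts in place of the index 36 (SRB4) to 1286 (GPD3) genes passed for treatment. SRB4 shifted by 1.06 in wild type and 0.79 in the deletion, which leaves its fit little precision. For strain 8 (SRB4, 2 higher and 6 lower) to 1245 (TFIID, 518 higher and 727 lower) passed. With an estimated correlation 0 lists moved in each of the 5 contrasts, against 13, 10, 8, 7 and 6 at the preset correlation. In wild type the histone and respiration lists had estimated correlations of -0.012 and -0.010, under the preset 0.01. Their camera adjusted p still went from 0.0165 and 0.0385 to 0.306. The lost calls therefore do not measure gene correlation alone. By fry 21 moved in wild type, 19 in the deletion, 21 in the interaction and 22 between treated strains.

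Among these values, which leave out list members named by the rule but given no value in the report, signs changed as follows. The common treatment effect with the index was against the wild type sign for pop8 (-0.14), csm1 (-0.33), mhf1 (-0.26), stc1 (-0.020), mrpl44 (-0.069), erg31 (0.72), psu1 (0.046), coq10 (0.73), htb1 (0.54), pap1 (-0.51), trr1 (0.25), caf5 (0.70), pgr1 (0.45), zym1 (-1.28), sty1 (0.52), cdc25 (0.11), abc2 (0.68), ags1 (0.48), bgs4 (0.38), bip1 (0.66), ccs1 (0.85), cdt2 (0.84), cyt1 (0.58), erg25 (0.74), gar2 (1.18), ght1 (0.38), gst2 (0.74), idh1 (0.70), lys4 (0.84), lys7 (0.59), mas5 (0.79), met6 (0.24), php4 (0.28), pof1 (0.10), rip1 (0.91), rpl4101 (-0.10), rpt5 (0.58), rrp6 (-0.45), sam1 (1.50), ser2 (0.86), sre2 (0.13), sur2 (0.51), tim18 (0.45) and vcx1 (0.98), and for sty1, cdc25, erg31, htb1, php4 and tim18 also against the deletion sign. The deletion sign was compared only for genes given a log2 change in the deletion. Others of these genes, such as coq10, ght1, rpt5 and rip1, also had lower means in treated than in control deletion arrays, while ccs1 did not. The common treatment effect of pap1 includes the deletion arrays, where the gene was under background, so it does not measure pap1 in wild type. The strain effect was against the control sign for pgr1 (0.070), gpd1 (0.11) and sty1 (0.13) and against the treated sign for trr1 (-0.066), hsp9 (0.00015) and ntp1 (-0.086). After quantile normalization pgr1 in wild type was 0.032, the interactions of hsp16, ntp1 and atf1 were 0.0070, -0.021 and -0.011, and trr1 and ntp1 between treated strains -0.069 and -0.11; ntp1 was -0.059 with centred arrays. With each array left out in turn, the control strain values of caf5 ran from -0.12 to 0.21, below 0 without wild type control replicate 1 (-0.12) and deletion control replicate 1 (-0.058), and those of gpx1 from -0.048 to 0.0048, the latter without deletion control replicate 1. The treated strain values of ntp1 ran from -0.00037 (without wild type treated replicate 1) to 0.0089, and those of atf1 from -0.19 to 0.013 (without deletion treated replicate 1). Except for pgr1 in wild type, no value that changed sign under quantile normalization, centring or a left-out array had passed the threshold.

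Leaving out each array in turn gave 2138 to 2329 genes in wild type, 1467 to 1898 in the deletion, 1460 to 1742 in the interaction, 108 to 660 between control strains and 1673 to 1825 between treated strains. The control strain count was 108 and 127 without wild type control replicates 1 and 2, and 113 and 135 without deletion control replicates 1 and 2. The lists that moved numbered 12 to 13, 9 to 11, 7 to 10, 5 to 7 and 5 to 7 in the same order, and the correlation between strains was 0.776 to 0.794. Without both treated wild type arrays 1898 genes changed in the deletion and 660 between control strains.

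The labels number the replicates 1 and 2 in each group without saying what a number shares. With the number as a replicate block 2289, 1736, 1663, 366 and 1861 genes passed, and within strain 2250, 1659 and 1556 in the first 3 contrasts. Deviations of arrays with the same number correlated over genes at -0.040 in wild type and -0.26 in the deletion. Crossed numbers in the deletion as a replicate block gave 1829 genes there and 1752 in the interaction.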

Other observations

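Of the 1451 genes that changed the same way in both strains, 80.0% changed more in wild type. Single genes among the others, chosen after their values were seen, are given here as log2 changes in wild type and deletion. Higher after treatment were ctr4 (0.49 and 1.49), adh4 (0.72 and 1.37), str1 (0.27 and 1.07), grx4 (0.85 and 1.17), pho4 (0.52 and 1.22), dea2 (1.08 and 1.24), mis13 (0.25 and 0.86) and alg6 (0.36 and 0.89). Lower after treatment were mvp1 (-0.70 and -1.34), vps20 (-0.82 and -1.22), ght3 (-0.44 and -0.99), pst1 (-0.59 and -1.04), tcb2 (-1.39 and -1.55) and bfr1 (-1.39 and -1.61).

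Arrays of the same group correlated over the 2896 S. pombe genes at 0.998 to 0.999, and arrays of different groups at 0.942 to 0.994. The mean of the hybridization controls was 8.37 ± 0.07 (log2, mean ± SD, n = 2) in wild type control, 9.49 ± 0.11 in wild type treated, 8.30 ± 0.11 in deletion control and 8.41 ± 0.13 in deletion treated arrays. Of 5390 probe sets with no gene name 1078 changed under treatment in the deletion and 84 between control strains, and of 2601 S. cerevisiae probe sets 51 and 1 did.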
